A study of Homo sapiens with 9 samples.

How the data were processed

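Total RNA from 9 cultures of PMA-differentiated THP-1 cells was measured, 3 each with vehicle, 0.5 µM cisplatin and 100 nM osimertinib for 16 h. Groups, doses, the time and replicate numbers were taken from the sample labels, which call the replicates independent and biological. Per the labels, each replicate was hybridised alone to an Affymetrix Human Gene 2.0 ST array after whole-transcript labelling, a service provider processed the scans with standard Affymetrix pipelines, and the values were summarized per gene. Affymetrix Power Tools is named in the submitters' processing notes without a version. The background correction, the summarization method and the log base are not given in the sources used here. The deposited values were read as log2 because all 9 columns run from 0.65 to 13.17, as log2 array intensities do; if the base were another, every fold in the text would change and the calls would not. The authors had normalized the arrays against each other, as seen from the values: at equal ranks the columns differed by 0.0268 on average. Such a normalization hides a change that shifts most transcripts one way, so changes are relative to the bulk of transcripts.

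The table has 53617 rows. The platform annotation used here, which can be old, names 16098 rows (30.0%) with 1 gene each, 0 with several, and leaves 37519 unnamed. All 16098 Entrez identifiers matched the RefSeq gene table of assembly GRCh38.p14, which gave current symbols and the class of each gene; 0 symbols had to be changed. Its positions were used only to find which non-coding transcripts lie inside a protein-coding gene on either strand. Of the 14884 genes, 779 had several rows, and the row with the highest mean over the 9 arrays was taken. The 7442 genes at or above the median of the gene means (4.28) were tested, a limit meant to leave out dim measurements; background and detection were not measured here. Exact ties occur in the values: 207 tested genes (2.78%) had 1 equal value on all 3 arrays of a group, which makes their spread look smaller than it is, and 1909 had at least 2 equal values within a group.

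The test was limma 3.58.1 in R 4.3.3: 1 linear model with 3 group means over the 9 arrays (6 residual degrees of freedom), empirical Bayes with a trend in the variance and robust fitting, and 3 contrasts (cisplatin minus vehicle, osimertinib minus vehicle, osimertinib minus cisplatin), plus a moderated F test over the groups. All p-values were two-sided, adjusted by Benjamini-Hochberg over the 7442 genes within a contrast, and called under 0.05. Standard errors are the moderated ones. The tests of each comparison, the gene lists, the rule for named genes and the alternatives, except those named below, were fixed before the data were examined. Fisher's exact tests on gene classes were not part of that plan, and other tests chosen later are named where they are given.

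The 47 gene lists held 1055 members, of which 568 were named in the table and 411 tested; 35 lists with at least 5 tested members entered limma's camera test with a preset correlation of 0.01 between genes. Camera compares a list with the other genes, and its p-values were adjusted over the 35 lists within a contrast. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the members of a list move one way on balance, without a comparison with other genes. The histone, proteasome and mitochondrially encoded lists had 0 named members and give no result. Members of a list are counted as rising or falling with the adjustment over all tested genes, and again adjusted over the list alone.

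The text names, for each drug against vehicle, the 10 largest rises and falls among called genes whose 3 treated arrays all lie on one side of the 3 vehicle arrays, up to 4 members of each described list with the smallest p, and 22 fixed genes; for the drugs against each other, the 5 largest each way. Further list members, mostly those that make up a count of called members, were named after their values were seen. Symbols of microRNAs, antisense and intronic transcripts, and provisional names were counted and not named under the first part. Nearly identical genes and pseudogenes can share probe sequences, and the array cannot part them.

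The comparisons with vehicle share 3 arrays. The covariance and correlation between them were set beside 100 simulated sets of 9 unchanged arrays with the fitted variances and independent genes. The fit was tested on simulated data with 200 changed genes among 7442: of genes changed by 1 log2 unit, 97.0% were recovered for cisplatin against vehicle, 98.5% for osimertinib against vehicle and 95.5% for the drugs against each other, and of those changed by 0.5 log2 units 59.7%, 59.7% and 64.2%. At 0.25 log2 units 14.9%, 10.4% and 13.4% were recovered. With no change simulated, 0 genes were called in each contrast. In a simulated shift of the chemokine list by -0.3, that list and 0 of the other lists were called. The simulated genes varied independently, so this run does not test how correlation between genes affects the list calls.

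Alternatives covered the level filter (none, or the 25th percentile), quantile normalization or median centring on top of the deposited values, all rows of the table, the mean over rows of a gene, empirical Bayes without trend and robust fitting, array weights, the replicate number as a block, each array left out in turn, a 1.5-fold minimum, and fits of only the groups compared. The restriction to protein-coding genes and the removal of genes with all 3 arrays of a group equal were added after the data had been seen.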

Results

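Gene expression was measured in THP-1 cells, a human monocytic leukaemia line that takes on a macrophage-like form (M0) when exposed to the phorbol ester PMA. The differentiated cells were given vehicle, 0.5 µM cisplatin, a platinum drug that crosslinks DNA, or 100 nM osimertinib, a covalent inhibitor of mutant forms of the epidermal growth factor receptor, for 16 h. Each of the 3 groups had 3 replicates that the labels call independent and biological, and each replicate was hybridised to 1 Affymetrix Human Gene 2.0 ST array, so 9 arrays were compared. The deposited values lie on a log2-like scale from 0.65 to 13.17, and the median over all rows was 3.29 to 3.37 on the 9 arrays. Of 53617 rows, 16098 were named with 1 gene, which gave 14884 genes. The 7442 genes at or above the median level of 4.28 were tested. For arrays no read depth exists, and the number of arrays limits the precision.

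The drug-treated arrays lay together and apart from the vehicle arrays. The first principal component held 57.7% of the variance, with the vehicle arrays at -21.2 to -19.6 and the 6 treated arrays at 7.70 to 12.2. Arrays of cisplatin and osimertinib correlated with each other at 0.974 to 0.985, and vehicle arrays with cisplatin arrays at 0.944 to 0.954. The second component held 12.1% of the variance, and its extremes were cisplatin replicate 1 at 15.5 and osimertinib replicate 1 at -11.2.

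**Figure D1:**
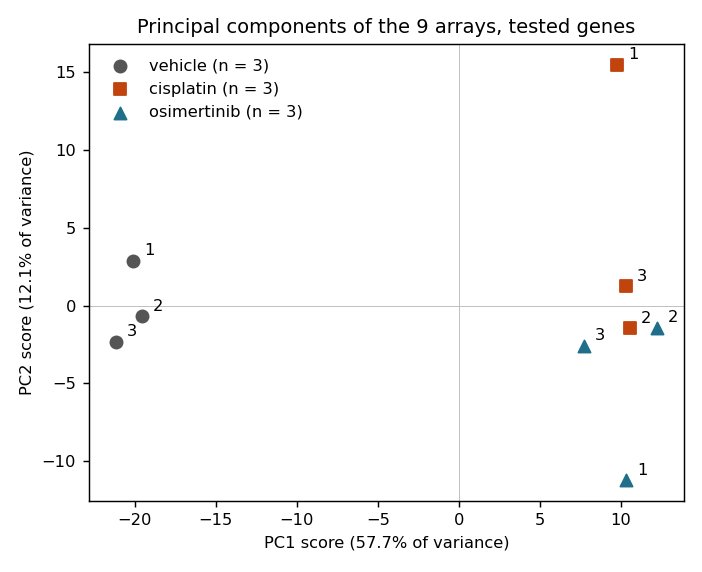
Scores of the 9 arrays on the first 2 principal components of the 7442 tested genes (axes: component scores, with the percent of variance; numbers beside the points are replicate numbers). The vehicle arrays sit at -21.2 to -19.6 on the first component and the treated arrays at 7.70 to 12.2, while cisplatin replicate 1 and osimertinib replicate 1 stand at 15.5 and -11.2 on the second.

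The first comparison asked which transcripts differed between cisplatin-treated and vehicle-treated macrophage-like cells. The largest rise was in CCL5, a chemokine that attracts T cells and monocytes, which was 14.4-fold higher (Entrez gene 6352; log2 fold change 3.85, SE 0.060, adjusted p = 5.3e-14, n = 3 and 3). Its log2 level was 6.28 ± 0.099 with vehicle, 10.13 ± 0.073 with cisplatin and 9.68 ± 0.019 with osimertinib (SD, n = 3 each). AQP9, a channel for water and glycerol, was 6.19-fold higher (2.63, SE 0.11), CCL22, a ligand of the chemokine receptor CCR4, was 5.62-fold higher (2.49, SE 0.058), and DUSP1, a phosphatase that switches off MAP kinases, was 4.24-fold higher (2.09, SE 0.066). The other large rises were in the antibacterial protein BPI (1.74), the Wnt receptor FZD8 (1.73), the carboxypeptidase CPA4 (1.68), the intermediate filament gene NES (1.67), the oxidised-lipoprotein receptor OLR1 and ARRDC4 (1.49). The largest falls among genes that could be named were in PMS2P9 (-1.86), SUMO4 (-1.83), the meiotic recombination gene MSH5 (-1.63), ADAM20P1 (-1.60), WASH5P (-1.57), ANKRD36B (-1.55), the centromere gene CENPI (-1.54), HMGA2, a chromatin-binding protein (-1.52), FRG1HP and NOTCH2NLA (-1.49). These 20 genes were picked among those whose 3 cisplatin arrays lay on one side of the 3 vehicle arrays, which held for 42.3% of tested genes. The genes PMS2P9, ADAM20P1, WASH5P and FRG1HP are transcribed pseudogenes, ANKRD36B and NOTCH2NLA have close copies, and SUMO4 lies within the gene TAB2, so their probes may not be specific to them.

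Across all tested genes, 2308 of 7442 changed with cisplatin by limma with Benjamini-Hochberg adjustment, 1227 higher and 1081 lower. Of these, 321 were higher and 344 lower by at least 1.5-fold. Long non-coding RNAs and transcribed pseudogenes leaned lower: 76 of 256 tested long non-coding RNAs fell and 18 rose, and 36 of 123 transcribed pseudogenes fell and 11 rose, against 923 lower and 1167 higher among 6778 protein-coding genes. Of 252 microRNA transcripts 42 fell and 19 rose, and the share that fell did not differ from that of the other genes (Fisher's exact test, adjusted p = 0.353). With quantile normalization on top of the deposited values the split moved to 1968 higher and 975 lower.

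Genes of the heat shock response, which encode chaperones, rose as a group with cisplatin: 6 of 8 measured members rose and 0 fell, before and after adjustment over the list alone (camera with a preset correlation, adjusted p = 1.63e-04; adjusted p = 0.551 with an estimated correlation). HSPA1B rose by 1.32 (SE 0.059), HSPA1A by 1.26 (SE 0.072) and HSPH1 by 0.84 (SE 0.048) on the log2 scale; HSPA1A and HSPA1B are near-identical copies whose probes cannot be taken as separate. Immediate-early genes, the first transcription factors and phosphatases induced by growth and stress signals, were higher in 6 of 12 and lower in 0, also over the list alone (adjusted p = 0.00122, and adjusted p = 0.551 with an estimated correlation). Besides DUSP1, these were JUN (1.41), EGR1 (0.92), FOS (0.84), JUNB (0.67) and KLF6 (0.40). Targets of NRF2, the regulator of the antioxidant response, were higher in 6 of 8 and lower in 0, also over the list alone (adjusted p = 0.00151, and adjusted p = 0.551 with an estimated correlation), with SRXN1 at 0.86, PGD at 0.71, HMOX1 at 0.66 and TXNRD1 at 0.37.

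Proliferation genes fell with cisplatin: 13 of 29 fell and 1 rose, or 14 and 1 adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.646 with an estimated correlation). BUB1, a mitotic checkpoint kinase, fell by 0.87, the replicative helicase subunit MCM4 by 0.54, PLK1 by 0.51 and TOP2A by 0.46, while AURKA rose by 0.35. Genes of DNA damage signalling and repair fell as well, 5 of 12 with 0 higher, also over the list alone (adjusted p = 0.0305, and adjusted p = 0.646 with an estimated correlation; adjusted p = 0.0523 without vehicle replicate 1). The members that fell were XRCC2 (-0.57), EXO1 (-0.48), MRE11 (-0.43), TOPBP1 (-0.38) and the checkpoint kinase CHEK1 (-0.32). The list of p53 targets was not called (adjusted p = 0.383): 3 of 15 rose and 3 fell, or 5 and 3 adjusted over the list alone, with SESN2 at 1.41, RRM2B at 0.47, CCNG1 at 0.26, FBXO22 at -0.51, GDF15 at -0.30 and SESN1 at -0.27. Some of these calls rested on single arrays: the highest adjusted p on leaving one out was 0.082 for GDF15 and 0.0902 for CHEK1 (both without vehicle replicate 2), 0.121 for MRE11 (without cisplatin replicate 1), 0.0516 for SESN1 (without vehicle replicate 3) and 0.159 for CCNG1 (without vehicle replicate 1). Without the level filter the calls of GDF15 (adjusted p = 0.0539), CHEK1 (0.0502), MRE11 (0.0685) and CCNG1 (0.0714) were lost, and so were those of MRE11 with quantile normalization on top (0.0506) and of GDF15 (0.0662) and CCNG1 (0.0532) without trend and robust fitting. The mean over all probe sets of FBXO22 gave -0.26.

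Among inflammatory lists, chemokines went both ways with cisplatin, 4 of 11 higher and 2 lower, also over the list alone, and the list was not called (adjusted p = 0.144). CCL3 and CCL4 were each higher by 0.65, whereas CXCL5, a neutrophil chemokine, fell by 1.34 and CXCL8 by 0.49. NF-kB targets were not called (adjusted p = 0.456), with 1 of 11 higher (BCL3, 0.37) and 3 lower (CCL20 at -0.58, IER3 at -0.45, IRAK2 at -0.33), also over the list alone. Of the 27 genes in this list 13 were named, and IL1B and IL6 were not. BCL3 was at an adjusted p of 0.0697 without cisplatin replicate 3 and IRAK2 at 0.132 without vehicle replicate 3, 0.0551 without the level filter and 0.0731 with quantile normalization on top. The mean over all probe sets of IER3 gave -0.20, which was not called (adjusted p = 0.0979). The type I interferon list was not called either (adjusted p = 0.702): BST2 (0.71) and OASL (0.68) rose and USP18 (-0.60) fell, 3 of 12, also over the list alone. M2-associated genes were at an adjusted p of 0.056, with 4 of 11 higher and 0 lower, also over the list alone: CD209 (1.19), PDCD1LG2 (0.98), FN1 (0.79) and VSIG4 (0.54). In the phagocytosis and efferocytosis list, not called (adjusted p = 0.468; median 0.047, mean -0.075), LRP1 (0.52) and SIGLEC10 (0.57) rose and MFGE8 (-1.04), CD47 (-0.54), MERTK (-0.44) and CD36 (-0.26) fell, which is 2 and 4 of 13, or 2 and 5 adjusted over the list alone. LXR and lipid efflux genes had 4 of 7 higher and 0 lower, also over the list alone (adjusted p = 0.0827), with APOC1 at 0.84, APOE at 0.53 and LPL at 0.44. ATF4 targets had 6 of 13 higher and 0 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.0729), with PSAT1 at 0.64 and AARS1 at 0.37. SESN2, given above with the p53 targets, is also in this list. Matrix and protease genes had 3 of 10 higher and 3 lower, also over the list alone (adjusted p = 0.952; median 0.077, mean -0.044). Of the 35 lists with at least 5 measured members, 5 were called with the preset correlation and 0 with an estimated one, where 1 had an unadjusted p under 0.05 (heat shock genes, 0.0339); the rotation test fry called 21.

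The second comparison asked the same of osimertinib against vehicle. CCL5 was again the largest rise, 10.6-fold (log2 fold change 3.40, SE 0.060, adjusted p = 2.7e-13, n = 3 and 3), followed by AQP9 (2.72, SE 0.11), CCL22 (2.36, SE 0.058) and DUSP1 (1.96, SE 0.066). The next were the chaperone gene HSPA4L (1.66), the peptidase AMZ2 (1.58), the glycosyltransferase GALNT12 (1.54), ARRDC4 (1.47), the sugar epimerase GALM (1.45) and NES (1.42). STC1, which encodes the secreted glycoprotein stanniocalcin-1, fell most, 6.90-fold (Entrez gene 6781; -2.79, SE 0.11, adjusted p = 2.07e-09). Its log2 level was 7.41 ± 0.089 with vehicle, 6.30 with cisplatin and 4.63 ± 0.23 with osimertinib (SD, n = 3 each). The 3 cisplatin arrays held 1 equal value for STC1, so its spread in that group is not known. All 3 groups share 1 estimate of the spread, so the SE and adjusted p of STC1 may be too small. DSPP (-1.99), TEX9 (-1.93), ADAM20P1 (-1.81), HMGA2 (-1.80), CXCL5 (-1.58), the opioid-like peptide precursor PNOC (-1.52), MSH5 (-1.52), the meiotic gene MND1 and PMS2P9 (-1.48) followed. All 20 genes were picked among those whose osimertinib arrays lay on one side of the vehicle arrays, which held for 44.1% of tested genes.

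With osimertinib, 2277 of the 7442 genes changed, 1255 higher and 1022 lower, and 351 were higher and 329 lower by at least 1.5-fold. Of 256 long non-coding RNAs 71 were lower and 17 higher, and of 123 transcribed pseudogenes 32 and 13. Of 252 microRNA transcripts 54 were lower and 11 higher, a larger share lower than among the other genes (Fisher's exact test, adjusted p = 0.00104). Quantile normalization on top gave 2005 higher and 932 lower, and median centring gave 1536 and 734.

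Heat shock genes rose with osimertinib in 7 of 8, or 8 adjusted over the list alone (camera adjusted p = 6.88e-06; adjusted p = 0.628 with an estimated correlation): HSPA4L (1.66), HSPA1A and HSPA1B (each 1.32), HSPH1 (0.92) and the small chaperone HSPB1 (0.69). NRF2 targets rose in 6 of 8, also over the list alone (adjusted p = 0.0162, and adjusted p = 0.709 with an estimated correlation), led by SRXN1 (0.80) and PGD (0.60). Immediate-early genes rose in 7 of 12, also over the list alone (adjusted p = 0.018, and adjusted p = 0.709 with an estimated correlation), with JUN at 1.39, FOS at 0.85 and EGR1 at 0.48. Targets of ATF4, the transcription factor of the integrated stress response, rose in 7 of 13, or 8 with 1 lower adjusted over the list alone (adjusted p = 0.0305, and adjusted p = 0.709 with an estimated correlation). They included the serine synthesis genes PSAT1 (0.98) and PHGDH (0.56), SESN2 (0.87) and the tRNA synthetase AARS1 (0.58). SESN2 is also in the list of p53 targets. LXR and lipid efflux genes rose in 3 of 7, or 4 adjusted over the list alone (adjusted p = 0.0274, and adjusted p = 0.628 with an estimated correlation): APOC1 (0.99), APOE (0.72) and LPL (0.47). Neither the ATF4 nor the LXR list differed between the drugs by the same test (adjusted p = 0.454 and 0.361). M2-associated genes rose in 5 of 11, or 7 adjusted over the list alone (adjusted p = 0.0437, and adjusted p = 0.777 with an estimated correlation), with CD209 at 0.67, FN1 at 0.64, PDCD1LG2 at 0.62 and VSIG4 at 0.57. That call ended with quantile normalization on top (adjusted p = 0.0917), and the M2-associated list did not differ between the drugs (camera adjusted p = 0.454).

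Proliferation genes fell with osimertinib in 14 of 29 and 1 rose, also over the list alone (adjusted p = 2.17e-04, and adjusted p = 0.709 with an estimated correlation). BUB1 fell by 1.11, PLK1 by 0.74, TOP2A by 0.69 and MKI67 by 0.49, and AURKA rose by 0.45. Genes of the extracellular matrix and its proteases fell in 5 of 10 and 1 rose, also over the list alone (adjusted p = 0.0368, and adjusted p = 0.709 with an estimated correlation): thrombospondin-1, THBS1, at -1.33, the collagenase MMP1 at -1.21, the cathepsin CTSK at -0.79, MMP19 at -0.32 and SPP1 at -0.25, against TIMP2 at 0.45. Of these, THBS1, CTSK and TIMP2 were not called in the test between the drugs over all genes. Of 35 lists, 8 were called with the preset correlation, 0 with an estimated one (2 at an unadjusted p under 0.05) and 20 by fry. Without vehicle replicate 1 the number was 5, with the ATF4 and matrix lists each at an adjusted p of 0.0607 and the M2-associated list at 0.0717. Without osimertinib replicate 3 the ATF4 and matrix lists stood at 0.0514, and the M2-associated list stood at 0.101 without osimertinib replicate 2 and 0.0629 without vehicle replicate 2. The DNA damage list had 5 of 12 lower, also over the list alone, at an adjusted p of 0.0673, and did not differ between the drugs (camera adjusted p = 0.541). The p53 list had 3 of 15 higher and 2 lower, or 4 and 2 adjusted over the list alone, at 0.276, with CCNG1 at 0.73 and RRM2B at 0.84. Chemokines had 2 of 11 higher and 2 lower, also over the list alone, at 0.94 (median -0.0085, mean 0.23). NF-kB targets had 1 of 11 higher and 3 lower, or 2 and 3 adjusted over the list alone (median 0.018, mean -0.17). Camera did not call the NF-kB list (adjusted p = 0.41), while fry called it as shifted down (adjusted p = 0.0227). Among genes of the pathway that osimertinib is aimed at, the ERK output list had 4 of 13 higher and 2 lower, also over the list alone, at 0.94 (median -0.033, mean 0.033), with MYC at 1.05, DUSP6 at 0.58, IER3 (also in the NF-kB list) at -0.92 and SPRY4 at -0.43. With cisplatin the ERK list had 4 higher and 1 lower (camera adjusted p = 0.344). Between the drugs 3 of its members were lower with osimertinib and 0 higher, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.205). The list of ERBB receptors and ligands had 3 of 6 higher and 1 lower, also over the list alone, at 0.606, with GRB2 at 0.50, SHC1 at 0.48 and ERBB4 at -0.40 (adjusted p = 0.0764 without vehicle replicate 3 and 0.0711 without osimertinib replicate 2). The mean over all probe sets of IER3 gave -0.44.

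**Figure D2:**
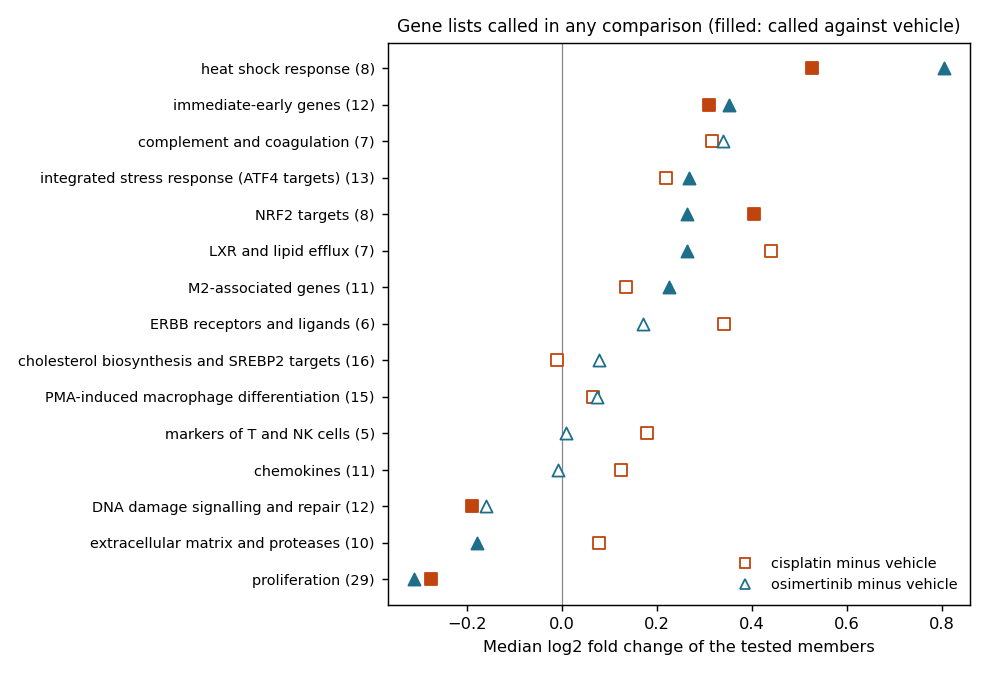
Median log2 fold change of the measured members of each gene list called in any of the 3 comparisons (x axis), for cisplatin (squares) and osimertinib (triangles) against vehicle; numbers in brackets are measured members, and filled symbols are lists called with the preset correlation. Heat shock genes have the highest medians, 0.53 and 0.80, and proliferation genes the lowest, -0.28 and -0.31.

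Most genes called with 1 drug were also called, in the same direction, with the other. Of the tested genes, 1743 were called in the same direction with both, 939 higher and 804 lower, 560 were called with cisplatin alone and 529 with osimertinib alone, which is not a test of a difference, and 5 were called in opposite directions: MMP19 (0.57 with cisplatin and -0.32 with osimertinib), S100A9 (0.50 and -0.33), ADGRG1 (0.28 and -0.56), PLXDC2 (-0.23 and 0.25) and ZNF740 (-0.24 and 0.26), of which the last 3 were picked out after their values were seen. Leaving out 1 array ended the call of ADGRG1 with cisplatin (adjusted p up to 0.161, without cisplatin replicate 2), of ZNF740 with cisplatin (0.133, without that array) and osimertinib (0.0908, without osimertinib replicate 1), and of S100A9 with osimertinib (0.196, without osimertinib replicate 2). Without the level filter ADGRG1 (adjusted p = 0.0702) and ZNF740 (0.0665) were not called with cisplatin nor S100A9 (0.0815) with osimertinib, and with quantile normalization on top ZNF740 was at 0.124 with cisplatin and S100A9 at 0.123 with osimertinib. Independent lists of these sizes would share 207 higher and 148 lower genes. The log2 fold changes correlated across genes, which are not independent replicates, at a Pearson r of 0.892 and a Spearman rho of 0.863. Both comparisons use the same vehicle arrays, and unchanged groups simulated against them gave an r of 0.50 on average over 100 runs. The covariance was 0.117 against 0.00678 in those runs, in which genes varied independently of each other. The 3 vehicle arrays are too few to be parted between the comparisons with at least 2 in each, so part of the excess over the chance value may still come from them.

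**Figure D3:**
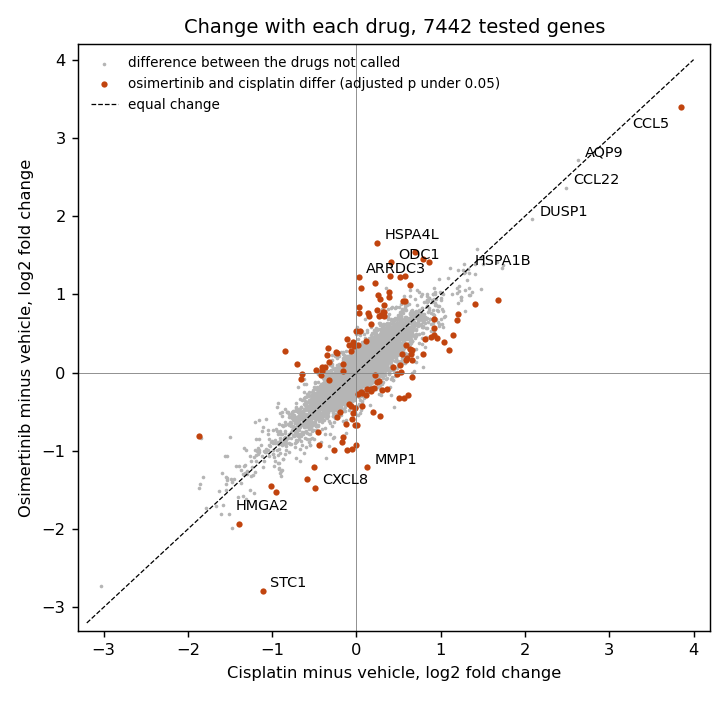
Log2 fold change with osimertinib (y axis) against that with cisplatin (x axis), each minus vehicle, for the 7442 tested genes; red points are the 130 genes that differed between the drugs, and the dashed line marks equal change. CCL5, AQP9, CCL22 and DUSP1 lie far up along the line, while STC1 (-2.79 with osimertinib) lies far below it and HSPA4L (1.66) above it.

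The third comparison tested the difference between the drugs. Osimertinib-treated cells had more HSPA4L (1.41, SE 0.16, adjusted p = 4.77e-04, n = 3 and 3), more of the arrestin-domain gene ARRDC3 (1.19, SE 0.10), ZNF138 (1.12, SE 0.15), the choline-lipid enzyme GPCPD1 (1.02, SE 0.12) and ODC1, the first enzyme of polyamine synthesis (1.00, SE 0.11). They had less STC1 (-1.67, SE 0.11, adjusted p = 5.84e-06), MMP1 (-1.34, SE 0.17), CXCL8, the chemokine interleukin-8 (-0.98, SE 0.12), the lectin CD22 (-0.92, SE 0.11) and NRIP3 (-0.92, SE 0.10). These 10 genes were picked among those whose 3 osimertinib arrays lay on one side of the 3 cisplatin arrays, which held for 14.3% of tested genes. The equal cisplatin values of STC1 may make its SE and adjusted p too small here as well. CXCL8 held 1 equal value (6.71) on cisplatin replicates 2 and 3. In total 130 of 7442 genes differed, 57 higher and 73 lower with osimertinib, and 127 of them had also been called with at least 1 drug against vehicle.

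Chemokines were lower with osimertinib than with cisplatin: 3 of 11 were lower and 0 higher, or 5 and 0 adjusted over the list alone (camera adjusted p = 2.72e-05; adjusted p = 0.0715 with an estimated correlation). The 3 were CXCL8, CCL4 (-0.71) and CCL5 (-0.45). CCL3 differed by -0.66 at an adjusted p of 0.0825 over all genes; its near-identical copies may share its probes. Matrix and protease genes were lower in 4 of 10, or 5 with 1 higher adjusted over the list alone (adjusted p = 0.00122, and adjusted p = 0.415 with an estimated correlation), namely MMP1, MMP19 (-0.89), the inhibitor TIMP1 (-0.37) and SPP1 (-0.31). Complement and coagulation genes were lower in 3 of 7, or 4 with 1 higher adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.473 with an estimated correlation): TFPI (-0.52) and THBD (-0.43), both anticoagulant, and the receptor C5AR2 (-0.36). PMA-induced genes were lower in 2 of 15 (EGR1 at -0.44, SPP1), or 7 with 2 higher adjusted over the list alone (adjusted p = 0.0336, and adjusted p = 0.81 with an estimated correlation). ERBB receptors and ligands were lower in 1 of 6, also over the list alone (HBEGF, a ligand of the epidermal growth factor receptor, at -0.26; adjusted p = 0.0294, and adjusted p = 0.415 with an estimated correlation). The cholesterol synthesis list was shifted up (adjusted p = 0.0336, and adjusted p = 0.673 with an estimated correlation), though 0 of its 16 members passed the test over all genes and 2 did adjusted over the list alone. The list of T and NK cell markers was shifted down (adjusted p = 0.0123, and adjusted p = 0.415 with an estimated correlation) through PRF1 (-0.90) and NCAM1 (-0.41), 2 of 5, also over the list alone. Leaving out 1 array ended several of these single calls: the highest adjusted p was 0.184 for CCL4 (without osimertinib replicate 1), 0.131 for TIMP1 and 0.164 for C5AR2 (both without osimertinib replicate 2), 0.119 for TFPI and 0.0905 for NCAM1 (both without cisplatin replicate 3), and 0.0676 for THBD and 0.0973 for HBEGF (both without cisplatin replicate 2). Without the level filter CCL4 (0.141), TFPI (0.0649), C5AR2 (0.11) and TIMP1 (0.0992) were not called, and without trend and robust fitting neither were CCL4 (0.106), THBD (0.0876), HBEGF (0.161), SPP1 (0.12), C5AR2 and TIMP1 (each 0.125).

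Of 35 lists, 7 were called with the preset correlation, 0 with an estimated one (4 at an unadjusted p under 0.05) and 2 by fry. The number of genes that differed between the drugs depended on single arrays and on the scaling. It was 147 without cisplatin replicate 1, 35 higher and 112 lower with osimertinib, 54 without cisplatin replicate 3, 67 without cisplatin replicate 2, and 76, 75 and 76 without osimertinib replicates 1, 2 and 3. Median centring gave 85 genes, 48 higher and 37 lower. List calls fell from 7 to 4 without cisplatin replicate 2 or 3, and those on cholesterol, ERBB and PMA-induced genes were each lost without 1 of at least 4 treated arrays, with the highest adjusted p at 0.0861, 0.0732 and 0.088; the T and NK marker list was at 0.0588 without cisplatin replicate 1.

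**Figure D4:**
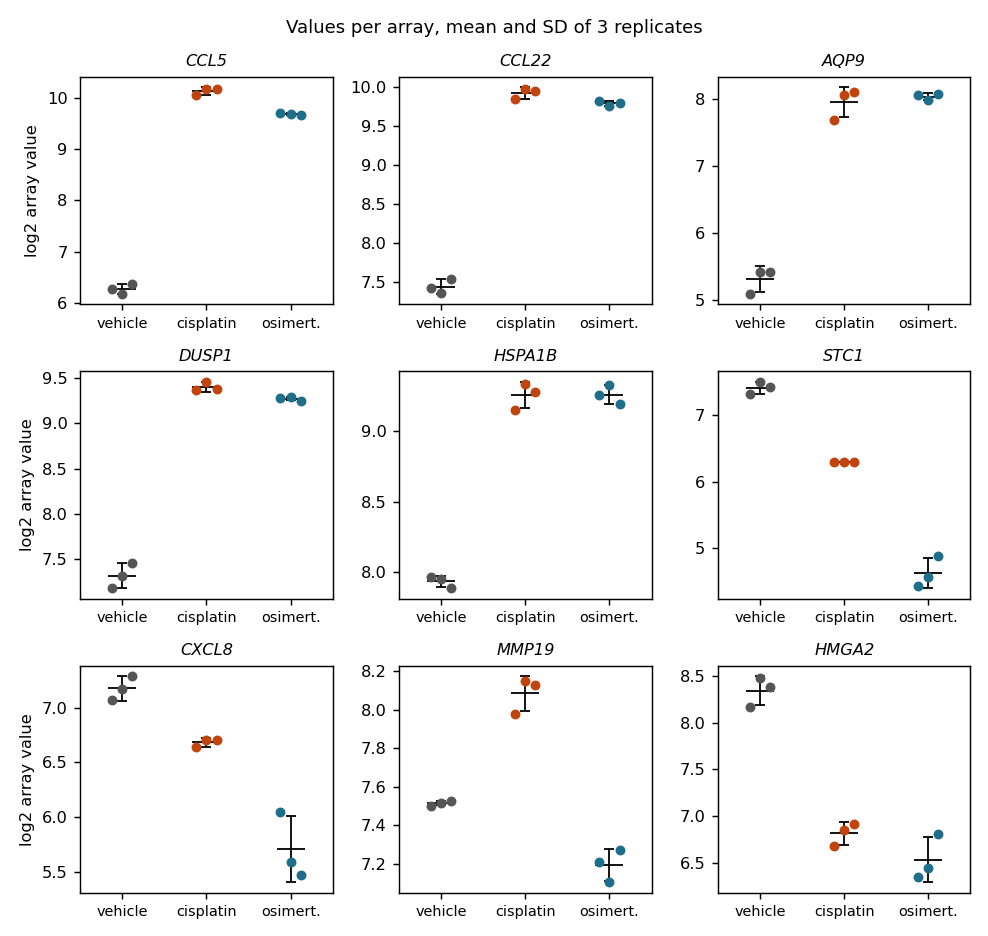
Log2 array values of 9 genes in the 3 groups (y axes, each with its own range); points are single arrays and bars are the mean and SD of 3 replicates. CCL5, CCL22, AQP9, DUSP1 and HSPA1B are higher with both drugs, STC1 and CXCL8 are lowest with osimertinib, MMP19 is higher with cisplatin and lower with osimertinib, and HMGA2 is lower with both.

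Of 22 genes fixed in advance, 8 were tested, 7 lay below the level filter and 7 were not named by the annotation used here. The phagocytosis checkpoint ligand CD47 fell by 0.54 with cisplatin and by 0.60 with osimertinib (SE 0.090), and the efferocytosis receptor MERTK fell by 0.44 and by 0.52 (SE 0.060). GDF15 was at -0.30 and -0.33 (SE 0.088), both called, the first at an adjusted p of 0.082 without vehicle replicate 2. SIRPA, the receptor of CD47, was at 0.11 and 0.032 and was not called (adjusted p = 0.30 and 0.789), whereas the mean over all its probe sets gave 0.27 and 0.22, both called (adjusted p = 0.0194 and 0.0478). TNF (-0.17 and -0.10), MT2A (-0.16 and -0.17) and HMGCS1 (0.045 and 0.17) were not called, with adjusted p of at least 0.0678. HMGCS1 with osimertinib was called with quantile normalization on top (0.20, adjusted p = 0.0137), and at an adjusted p of 0.0466 without cisplatin replicate 1 and 0.035 without osimertinib replicate 3. The genes below the filter were fitted with all 14884, and whether their signal exceeds background was not measured. The immune checkpoint ligand CD274, at levels of 2.99 with vehicle, 4.04 with cisplatin and 3.74 with osimertinib, had changes of 1.05 (SE 0.13, adjusted p = 3.07e-04) and 0.75 (adjusted p = 0.00256). With cisplatin the values were 0.62 for CD86 (levels 2.92 and 3.54, adjusted p = 0.0305), 0.52 for IL10 (2.13 and 2.65, adjusted p = 0.00399) and 0.41 for CXCL10 (2.24 and 2.65, adjusted p = 0.0304). With osimertinib they were 0.26, 0.25 and -0.13, with adjusted p of 0.398, 0.136 and 0.521. Their difference between the drugs was not called (adjusted p = 0.607, 0.43 and 0.0802). EGFR, the main target of osimertinib, was at -0.016 and -0.0024 with adjusted p of 0.951 and 0.994, at levels of 2.89, 2.88 and 2.89 with vehicle, cisplatin and osimertinib.

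The marker lists of other cell types had median levels below the filter at 4.28, and all but the fibroblast list had members above it. The median level over measured fibroblast markers was 2.48 with vehicle, 2.64 with cisplatin and 2.37 with osimertinib, and over neutrophil markers 3.10, 3.59 and 3.53. The T and NK cell markers stood at 4.08, 4.15 and 3.99, with 5 of 11 above the filter and NCAM1 brightest at 6.49, 6.67 and 6.26. Epithelial markers had medians of 3.35, 3.44 and 3.29, with 5 of 14 above the filter and KRT18 brightest at 7.71, 7.36 and 7.40. B cell markers had medians of 3.12, 3.32 and 3.21, with FCRLA at 6.12, 6.48 and 5.91, and endothelial markers 3.55, 3.45 and 3.58, with ESAM at 5.55 to 5.68 in the 3 groups. Erythroid markers had medians of 3.50, 3.69 and 3.54, with GATA1 at 4.73, 4.95 and 4.76. The median over markers of undifferentiated monocytic and progenitor cells was 3.63, 3.45 and 3.61, with 3 of 11 above the filter and GFI1 brightest at 6.19, 6.31 and 6.05.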

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

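The tests on the shared vehicle arrays, the normalization, the position of the non-coding transcripts and the chemokine and matrix genes were chosen only after the results were seen; the level test and the regrouping of arrays were planned. The gene lists, the tests of each comparison and the settings compared in the next part, with the exceptions named there, were set before the data were examined.

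With both drugs 1743 genes were called in the same direction, with cisplatin alone 560, with osimertinib alone 529 and in opposite directions 5. Chance variation of single genes on the 3 shared vehicle arrays is argued against as the whole cause by the covariance of the fold changes, 0.117 against a highest simulated value of 0.00727. The simulated genes varied independently, so this test cannot decide on variation of the vehicle arrays that many genes share. An offset of the kind that quantile normalization removes is argued against as the whole cause: applied on top it raised the share of higher calls by 13.7 points with cisplatin and 13.2 with osimertinib, yet kept 94.1% of the shared calls. The labels name no batch, so whether the vehicle arrays were handled apart from the treated ones was not tested. A response of these cells to both drugs is a candidate explanation.

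For cisplatin against vehicle 1 of 10 splits of the 6 arrays gave as many genes as the real one (2308; highest other 0), for osimertinib 1 of 10 (2277; highest other 0) and for osimertinib against cisplatin 1 of 10 (130; highest other 0), and 10 splits are too few for a share under 0.05. Over the 3 groups together, 1 of 100 splits drawn of 280, the real one, gave as many as 2407, which argues against a chance split for that count. The count cannot tell a drug response from another difference between vehicle and treated arrays, such as their handling. The highest other split gave 2333 and keeps the vehicle arrays together, which points to the structure of vehicle against treated arrays; splits that part the vehicle arrays gave at most 11.

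Many measured features have no gene name in the annotation used here. Among all 37519 of them, 3147 differed between cisplatin and vehicle, 828 higher and 2319 lower, and 2953 between osimertinib and vehicle, 811 higher and 2142 lower. At or above the level filter 10112 were left, of which 3002 and 2960 differed, 64.0% and 63.6% of them lower.

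Named non-coding and pseudogene transcripts together leaned lower as well, though microRNAs did not pass that test with cisplatin (adjusted p = 0.353) and the 33 of other classes leaned higher, 12 higher and 4 lower with cisplatin and 9 and 2 with osimertinib. Their low level is argued against as the whole cause on these arrays. Against 10 level-matched protein-coding genes each, their median change was lower by a difference of -0.091 with cisplatin (95% bootstrap interval -0.13 to -0.052, 664 transcripts) and -0.14 with osimertinib (-0.18 to -0.096). The bootstrap intervals in this paragraph resample transcripts and not arrays, so they leave out the spread between replicates. Less intron-containing RNA in the treated preparations stays open: relative to those matched genes, the median of 248 transcripts inside protein-coding genes minus that of 416 outside was 0.093 with cisplatin (-0.0045 to 0.17) and 0.048 with osimertinib (-0.030 to 0.13), whereas that explanation expects a value under 0. The 416 outside leaned lower by themselves, at -0.12 (-0.18 to -0.067) and -0.16 (-0.21 to -0.10). The cause of the lean was not found.

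The effects of the 2 drugs differed in 130 genes by a test of the difference itself. By the preset-correlation list test they differed for chemokines (adjusted p = 2.72e-05), matrix and protease genes (0.00122), complement and coagulation genes (0.0123), T and NK cell markers (0.0123), ERBB receptors and ligands (0.0294), PMA-induced genes (0.0336) and cholesterol synthesis genes (0.0336), and with an estimated correlation for 0 of these.

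The chemokine and matrix lists were taken further because they had the smallest p for the difference between the drugs; over their 21 tested genes the median difference was -0.23, and 7 were called lower with osimertinib. Cisplatin replicate 1, which stands apart on the second component, is argued against as the whole cause, because the median without it was -0.22. Both lists were still called without it, though at their highest adjusted p on leaving 1 array out (camera, 0.00442 for chemokines and 0.00867 for matrix genes). Without osimertinib replicate 1, the other extreme of that component, camera gave 7.71e-04 and 0.00137, and the median was not examined. Fewer differentiated cells with osimertinib may contribute and stay open: 14 other PMA-induced genes had a median of -0.11 (-0.21 to 0.075), 0.12 above that of the 21 genes, with an interval of -0.12 to 0.42. Lower output of NF-kB was not decided. The 11 targets outside the lists had a median of 0.054, with 4 lower with osimertinib, but the interval, -0.29 to 0.12, also holds the -0.23 to be explained. A drug-specific effect on these genes was not tested further. The intervals in this paragraph resample genes and not arrays, so they leave out the spread between replicates.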

How the results depend on the processing

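Restricting the fit to protein-coding genes and leaving out genes with tied arrays were chosen only after the results were seen; the other alternatives were planned. Testing every measured feature also drops the level filter and the choice of 1 feature per gene, and plain empirical Bayes drops both trend and robust fitting; of 144 for the counts, 115 stayed within 1.5 times the reported count. The cause of the other shifts was not tested, except where fewer arrays or a stricter limit enter. Testing every measured feature gave 5295 changes with cisplatin (1870 higher), 5144 with osimertinib (1857 higher), 35 between the drugs and 5102 over the 3 groups. A fold of at least 1.5 left 665, 680, 45 and 879. Between the drugs the count was 76 with no level filter, 218 with quantile normalization, 85 with median centring, 63 with plain empirical Bayes, 349 with array weights (101 higher, 248 lower) and 77 with only those 2 groups. Leaving out 1 array gave 1813 to 2269 genes with cisplatin, 1828 to 2497 with osimertinib, 54 (without cisplatin replicate 3) to 147 (without cisplatin replicate 1) between the drugs, 1877 to 2501 over the 3 groups and 1416 to 1775 shared. Where a group is left with 2 arrays they share the spread of the others.

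Called lists numbered 9 for cisplatin with no level filter against 5; with an estimated correlation 0, 0 and 0 for cisplatin, osimertinib and their difference, and by fry 21, 20 and 2. Leaving out 1 array gave 4 to 6 lists for cisplatin, 5 (without vehicle replicate 1) to 9 for osimertinib and 4 (without cisplatin replicate 2) to 7 for the difference. Of 140 alternatives for single called lists 104 kept the call. Quantile normalization moved the median of all genes to 0.11 with each drug and median centring to 0.10 with osimertinib. The replicate numbers did not pair the arrays; as a block they gave 2155, 2145 and 108 genes and 1629 shared.

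Directions reversed, with no call, in SIRPA with osimertinib (-0.038) and, between the drugs, in GDF15 (0.013), TNF (-0.029) and MT2A (0.074), each on leaving out 1 array. SIRPA was called with both drugs when the probe sets of a gene were averaged (0.27 and 0.22), and HMGCS1 with osimertinib under quantile normalization (0.20). Of 438 settings for 73 fixed genes and largest changes 427 kept side and direction. Among 354 other called list members and genes of opposite direction 1843 of 2124 did and 281 lost the call in the same direction. Protein-coding genes alone gave 2143, 2139 and 144 genes, and leaving out the 207 genes with all 3 arrays of a group equal gave 2289, 2270 and 131. Background was not measured, so what the signal allows in the 7442 dim genes not tested is not known, and in simulated data 14.9% of changes of 0.25 were recovered with cisplatin.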

Other observations

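The lists in this part were fixed in advance, and no test was chosen after the results were seen; the genes named are called members with small p. Autophagy genes went both ways with both drugs: 4 of 18 rose and 2 fell with cisplatin (5 and 2 adjusted over the list alone, adjusted p = 0.528), and 7 rose and 2 fell with osimertinib (7 and 2, adjusted p = 0.276). GABARAPL1, which takes part in forming autophagosomes, rose by 1.28 and 1.38, while its relative GABARAP fell by 1.08 and 0.98 and ATG7, which activates this family, fell by 0.66 with each drug. Lysosomal genes had 5 of 17 higher and 2 lower with cisplatin (6 and 3 adjusted over the list alone, adjusted p = 0.299) and 6 and 2 with osimertinib (7 and 2, adjusted p = 0.159), with the cathepsin CTSZ at 0.99 and 1.03.

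Hypoxia and glycolysis genes had 5 of 13 higher and 0 lower with cisplatin (6 and 0 adjusted over the list alone, adjusted p = 0.116), and 3 and 1 with osimertinib (4 and 1, adjusted p = 0.271). HK2, a hexokinase, rose by 1.28 and 1.06. Ribosome biogenesis and MYC target genes had 5 of 16 higher and 0 lower with cisplatin (5 and 1 adjusted over the list alone, adjusted p = 0.116), and 5 and 2 with osimertinib (6 and 2, adjusted p = 0.184), with the nucleolar methyltransferase FBL at 0.97 and 0.78 and ODC1 at 0.41 and 1.41. Of 6 cell adhesion genes 2 rose with each drug (2 and 3 adjusted over the list alone, adjusted p = 0.144 and 0.117): the tetraspanin CD82 by 1.22 and 1.10 and ICAM3 by 0.68 and 0.63. Apoptosis regulators had 3 of 14 higher and 1 lower with cisplatin (3 and 1 adjusted over the list alone, adjusted p = 0.456) and 5 and 0 with osimertinib (5 and 1, adjusted p = 0.276), and MCL1, which holds back cell death, rose by 0.40 and 0.34.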
